A study of Mus musculus with 2 samples.

How the data were processed

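Spatial transcriptomes of mouse intestine were compared between 1 section labelled wild type and 1 section labelled Dpf2 knockout, both after 10 Gy of X-rays. Dpf2 encodes a subunit of the BAF (SWI/SNF) chromatin remodelling complex. Per the labels, fresh frozen tissue was cut into 10 µm sections, placed on an array of barcoded capture spots, and sequenced as paired reads of 150 bases on a NovaSeq instrument at a depth of at least 50000 reads per spot of 100 µm. The authors aligned the spot image with the bright-field image of the tissue and kept the barcodes under tissue. The submitters' processing notes name the genome build GRCm38. The aligner, the counting tool and any collapsing of molecular identifiers are not given in the sources used here. The same holds for the time after irradiation, the stretch of gut, the part of Dpf2 deleted, the tissue in which it was deleted, and the unit of the barcode positions. Below, a spot means 1 deposited barcode. The sections hold 50970 and 88056 of these, at medians of 721 and 932 counts. The 100 µm and the read depth of the label are not taken to describe them.

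The deposited values are whole-number counts per gene and barcode, taken here as the authors made them, with no normalisation. Because collapsing of molecular identifiers is not stated, the values are called counts. Floors and the intervals of CPM, ratios and shares cover counting error only. The matrix lists 54752 features with 54658 symbols, and the counts of the 94 features that repeat a symbol were added to the first. Of the symbols, 37720 (69.0%) occur once in the RefSeq annotation of GRCm38, from which chromosomes and positions were taken. The 2041 genes on chromosome X, the 334 on Y and the 37 encoded in the mitochondrial genome hold 0 counts in both sections, which leaves them and the lists made of them without a value here.

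Counts were summed over all barcodes of a section and expressed as CPM, the counts of a gene per 1000000 counts of its section. Log2 ratios set the section labelled knockout over the section labelled wild type. CPM carry exact Poisson intervals, ratios carry exact conditional binomial (Clopper-Pearson) intervals, and shares of counts carry Clopper-Pearson intervals, all at 95%. Where 1 section holds 0 counts, its value was set to a floor of 3 counts in that section and the ratio is given as a bound. The floor is 0.0753 CPM in the section labelled wild type and 0.0334 CPM in the section labelled knockout. There are no replicates, so no test of a difference between genotypes was made, and spots were not used as replicates. Genes at least 2-fold apart were counted among genes with 200 or more counts over both sections. Each section was also split by position into 4 parts with about equal numbers of barcodes, and into square tiles with a side of 100 position units and at least 200 barcodes, which give a range within a section.

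Before the data were examined, 59 gene lists were fixed, 31 for functions and complexes and 28 for markers of cell types. For each list, the median log2 ratio was taken over members with 20 or more counts, if at least 3 had them. It carries an exact binomial interval of the median over the members, which covers the spread among them, treats them as independent and holds no counting error. Lists of fewer than 6 measured members, 4 in all, carry their range instead. The percentile of each median was found among 10000 random lists of the same size, matched on expression in 20 bins. Genes were named in the text by rules fixed at the same time. These are the subunits of the BAF complex, up to 5 members of each list with the largest ratios among those with 50 or more counts, and the 2 most abundant members of each list. They also include the 15 highest and 15 lowest ratios among genes whose 4 parts of 1 section all lie above those of the other, leaving out predicted genes, ribosomal protein genes, variable immunoglobulin and T cell receptor segments and haemoglobins. The 10 most abundant genes of each section, the 3 highest and 3 lowest ratios in each region with 100 or more spots of each section, and the 5 leading genes of each region complete the rules. Any other gene named is said to have been chosen after its values were seen. Some genes that these rules name are not reported here.

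Regions were sought over spots with 300 or more counts from both sections together. Counts were scaled to 10000 per spot and logged, and 2000 variable genes per section were joined, leaving out Dpf2 and mitochondrial, ribosomal protein, immunoglobulin, haemoglobin and sex-linked genes. The spots were then clustered on 30 principal components and 15 neighbours with the Leiden method at resolution 0.6, without integration. Ratios within a region were taken where it holds 100 or more spots of each section. Ratios were also taken over the spots whose share of pan-epithelial marker counts is at or above the median of all spots. Alternatives covered the scaling, the genes in the total, the minimum counts of genes and spots, the weight of spots, the spots summed, the summary of a list and the clustering settings. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

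The procedure was tested on simulated data built from these counts. Genes were drawn as Poisson counts around 1 rate shared by both sections, apart from the changes put in. The simulation thus holds counting error only, with no difference between animals, tissue or stretches of gut, and shows only that the steps compute what they should. Of 97 genes changed 4-fold and 97 changed 3-fold, 100% were found past the 2-fold limit in the right direction, and 0% of 14468 unchanged genes passed it. The intervals covered the true ratio for 95.4% of the unchanged genes. Of 200 random lists without a shift, 4% fell outside the central 95% of the matched lists. Of 200 lists shifted by 1 on the log2 scale, 100% passed the upper limit. The 3 simulated spot profiles were recovered from 2400 spots with an adjusted Rand index of 1. These profiles came from spots of the section labelled knockout with the highest enterocyte, smooth muscle or proliferation shares. They were split at random with no difference between sections, unlike the real spots.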

Results

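The series asks what DPF2 does in intestinal injury caused by radiation. It holds 2 sections of mouse intestine, 1 labelled wild type and 1 labelled Dpf2 knockout, each taken after 10 Gy of X-rays. The section labelled wild type holds 50970 barcodes under tissue with 39824941 counts in all, a median of 721 counts and 481 genes per barcode, and 28717 genes detected. The section labelled knockout holds 88056 barcodes with 89754886 counts, a median of 932 counts and 622 genes per barcode, and 30766 genes detected, so its total is 2.25 times that of the other. Each genotype has 1 section and neither has an unirradiated one. The differences described are therefore between these 2 sections, and they cannot be assigned to the genotype. Intervals of single genes and of shares of counts cover counting error only, and those of list medians cover the spread among the members.

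Dpf2 itself was not lower in the section labelled knockout. The gene (chromosome 19, 5896516 to 5912871 on GRCm38) had 940 counts, or 23.6 CPM, in the section labelled wild type and 2333 counts, or 26.0 CPM, in the section labelled knockout. The log2 ratio was 0.14 (95% counting interval 0.03 to 0.25). The measured level thus goes against the label, and every direction below is between the section labelled wild type and the section labelled knockout. Reads from outside the deleted part of the gene check nothing about a deletion, and that part is not given in the sources used here. The 28 subunits of the BAF complex had a median log2 ratio of 0.08 (−0.29 to 0.30), of either sign under the scalings tried and with a summed level at −0.15, and 26 of them lay within 2-fold. Dpf3, a relative of Dpf2 in the same complex, stood at 1.35 on 67 and 384 counts, and Ss18l1 at 1.11. The lowest were Smarce1 at −0.88, the core subunit Smarcc1 at −0.84 and Actl6b at −0.84. Smarca4, the ATPase of the complex, stood at −0.64, and Arid1a at 0.44.

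The sections differed in the kind of epithelium and in inflammatory cells. Genes of absorptive enterocytes were far higher in the section labelled knockout. Genes of Paneth cells, of neutrophils, of inflammatory signalling and of the list for regenerating epithelium were far higher in the section labelled wild type. Of 14516 genes with 200 or more counts, 2279 were at least 2-fold higher in the section labelled knockout and 2862 at least 2-fold lower. In 2253 and 2835 of these, all 4 parts of 1 section lay beyond all 4 parts of the other, and 496 and 340 genes were at least 8-fold higher and lower. The median log2 ratio of all these genes was −0.18. With scaling by the median of ratios, which sets this median near 0, the counts became 2733 higher and 2261 lower, so the balance of the directions depends on the scaling.

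Genes of enterocytes and of fat were among the highest ratios. Cfd, the adipocyte gene for complement factor D, had 8 counts in the section labelled wild type and 77508 in the section labelled knockout, a log2 ratio of 12.07 (11.09 to 13.28). Adipoq, the adipocyte hormone adiponectin, had 0 and 5720 counts and was at least 846-fold higher. Lct, the lactase of the brush border, stood at 9.85, Mbl2 at 9.66, the trehalase Treh at 9.46, Leap2 at 9.43 and the glucose transporter Slc2a2 at 9.23. The xenobiotic enzymes Cyp1a1, Cyp3a25 and Cyp2d26 stood at 9.10, 8.99 and 8.74, Car3 at 8.77, Fabp1 at 8.38 and Ugt2a3 at 8.10. Slc13a2os rested on 2 counts in the section labelled wild type with a ratio of 8.24 (6.38 to 11.28), and Slc47a1 on 3 counts with 8.03 (6.48 to 10.31). Neutrophil genes, chemokines that attract neutrophils and defensins were among the lowest ratios. Csf3, the growth factor of granulocytes, had 1287 counts in the section labelled wild type and 1 in the section labelled knockout, a log2 ratio of −11.50 (−16.81 to −9.02). Ly6g, a surface marker of neutrophils, had 2523 and 2 counts, a ratio of −11.47 (−14.52 to −9.62). Ngp stood at −10.69 (−15.99 to −8.21) and Cxcl3 at −10.39 (−15.70 to −7.91), each on 1 count in the section labelled knockout. Cxcl2 stood at −9.22, S100a8 at −8.12, Clec4d at −7.89, Cxcl1 at −7.84, Defa2 at −7.82, S100a9 at −7.76, Defa32 at −7.59, Defa21 at −7.58 and Defa20 at −7.57. Tff1 stood at −8.84 (−11.12 to −7.29) on 3 counts and Il1a at −8.21 (−11.26 to −6.34) on 2 counts in the section labelled knockout.

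**Figure D1:**
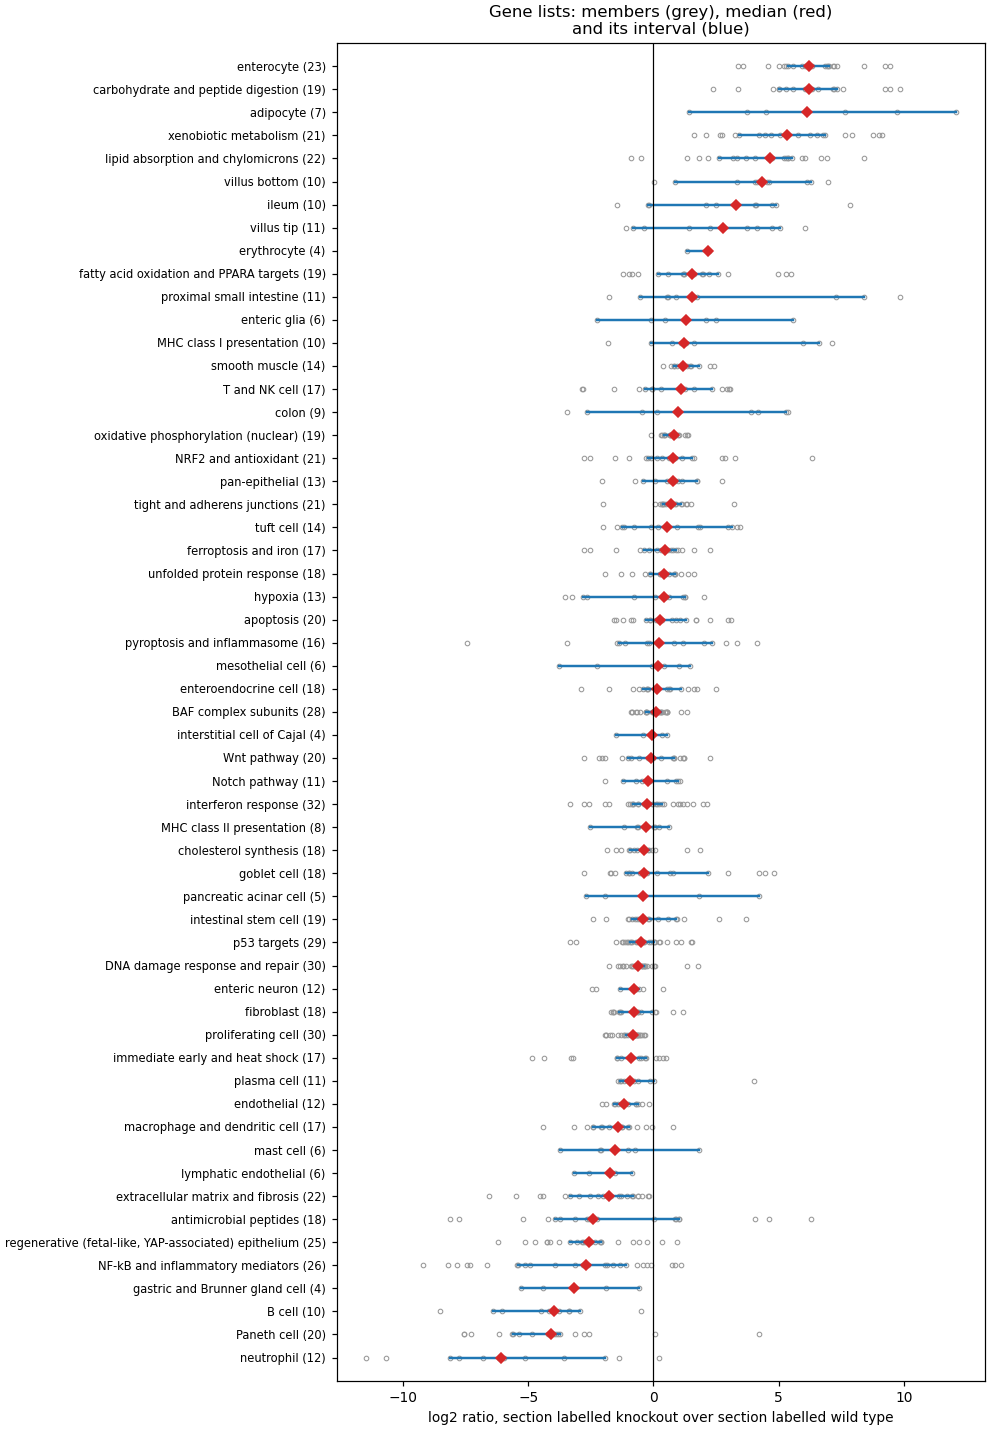
Log2 ratios of the section labelled knockout over the section labelled wild type for the members (grey) of each fixed list, with the list median (red) and its 95% interval, or its range for lists of fewer than 6 members (blue); measured members are in brackets. Medians run from 6.20 for enterocyte genes to −6.08 for neutrophil genes.

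Absorptive enterocytes take up sugars, peptides and fat across the brush border, and most of their genes were higher in the section labelled knockout. All 23 measured enterocyte markers were more than 2-fold higher there, with a median log2 ratio of 6.20 (5.38 to 7.01), above every one of 10000 matched random lists. Together they made up 0.0656% of counts (0.0648 to 0.0664) in the section labelled wild type and 3.65% (3.65 to 3.66) in the section labelled knockout. Fabp1, which carries fatty acids in the cell, had 15.3 and 5118 CPM, and Apoa1, the apolipoprotein of HDL, had 100.2 and 6167 CPM. The peptide transporter Slc15a1 stood at 7.31 and the amino acid transporter Slc6a19 at 7.21. Of the 24 enterocyte markers, 20 belong to other lists as well. All 19 genes of carbohydrate and peptide digestion were higher, with a median of 6.20 (5.02 to 7.31), among them the sodium-glucose transporter Slc5a1 at 6.13, the aminopeptidase Anpep at 6.32 and the fructose transporter Slc2a5 at 7.58. Of 22 genes of lipid absorption and chylomicrons, 20 were higher, with a median of 4.66 (2.61 to 5.54), including Apoa4 at 6.04, Apoc3 at 6.94 and the sterol transporter Npc1l1 at 6.70. Xenobiotic metabolism had a median of 5.33 (3.42 to 6.86) with all 21 genes higher, such as Cyp2b10 at 7.94, Ces2a at 7.66 and Cyp3a13 at 5.05.

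Genes that mark positions along the villus had medians above 0, with an interval that includes 0 for the tip. Villus-tip genes had a median of 2.79 (−0.82 to 5.07), with 8 of 11 higher, led by Apoa4, the adenosine deaminase Ada at 5.07, and Krt20 at 3.73. Genes of the villus bottom had a median of 4.34 (0.85 to 6.28), with all 10 higher, including the lectin Reg3b at 4.04, Reg1 at 6.28 and Gsdmc4 at 6.13, while Reg3g stood at 0.85. Genes of 3 stretches of gut had medians above 0, with intervals that include 0 for each. Genes of the ileum had a median of 3.27 (−0.21 to 4.89), with the phosphate transporter Slc34a2 at 7.85 and the bile acid transporter subunit Slc51a at 4.08. Genes of the proximal small intestine had a median of 1.53 (−0.55 to 8.38), with Lct, Fabp1 and Adh6a at 7.29, and with Slc34a1 at −1.78. Genes of the colon had a median of 0.99 (−2.64 to 5.30), with 6 of 9 higher, Slc26a3 at 5.30, Car4 at 3.90 and Retnlb at −2.64. Their median was −0.05 in spots with a pan-epithelial share of 1.27% or more. Pan-epithelial genes had a median of 0.77 (−0.41 to 1.73). Epcam stood at 1.74 and Vil1 at 2.75, but Krt18 at −2.06. Genes of tight and adherens junctions had a median of 0.70 (0.37 to 1.12), with 20 of 21 higher, Cldn15 at 3.21 and Cdh1 at 0.64, and with Cldn4 at −2.01.

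Paneth cells, which secrete antimicrobial defensins at the crypt base, had genes that were far lower in the section labelled knockout. Their 20 measured genes made up 12.5% of counts (12.47 to 12.49) in the section labelled wild type and 0.861% (0.859 to 0.863) in the section labelled knockout. The median log2 ratio was −4.09 (−5.61 to −3.74), below every one of the 10000 matched random lists, and 18 of 20 genes were at least 2-fold lower in the section labelled knockout. The defensins differed by unequal amounts. Defa24, the most abundant of them, had 36414 and 2722 CPM, a log2 ratio of −3.74, and Defa17 stood at −3.99, while Defa22 stood at −7.30, Defa5 at −6.18 and Defa29 at −5.66. The exceptions, named after their values were seen, were Guca2b at 4.22 and Pnliprp2 at 0.07, the latter of either sign under the scalings tried. The 18 antimicrobial peptides, 13 of them also in other lists, went both ways around a median of −2.40 (−3.94 to 1.0), with Pla2g2a at −5.22 and S100a8 at −8.12, but with the Reg lectins Reg1 at 6.28, Reg3a at 4.60 and Reg3b at 4.04. The predicted gene Gm7861, among the 10 most abundant genes of the section labelled wild type, stood at −4.69, beside Defa30 at −4.09 and Defa31 at −3.67.

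Other secretory lineages showed no common direction. Goblet cell genes had a median of −0.39 (−1.11 to 2.16), with the mucus proteins Fcgbp at 4.44, Clca1 at 4.81 and Zg16 at 4.21 higher and Spink4 at −2.76. Enteroendocrine genes had a median of 0.15 (−0.42 to 1.10), with Nts at 2.49, Gip at 1.73, Reg4 at −2.88 and Tac1 at −1.79. Tuft cell genes had a median of 0.55 (−1.27 to 3.12), with the channel Trpm5 at 2.97 and Pou2f3, their transcription factor, at −1.17. The summed levels of these 3 lists had the other sign than the medians, at 0.52 for goblet cell, −0.76 for enteroendocrine and −0.41 for tuft cell genes. Intestinal stem cell genes had a median of −0.44 (−0.85 to 0.88), with Olfm4 at 3.71 and Axin2 at 1.22 higher and Cd44 at −2.43 and Sox9 at −1.90 lower.

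**Figure D2:**
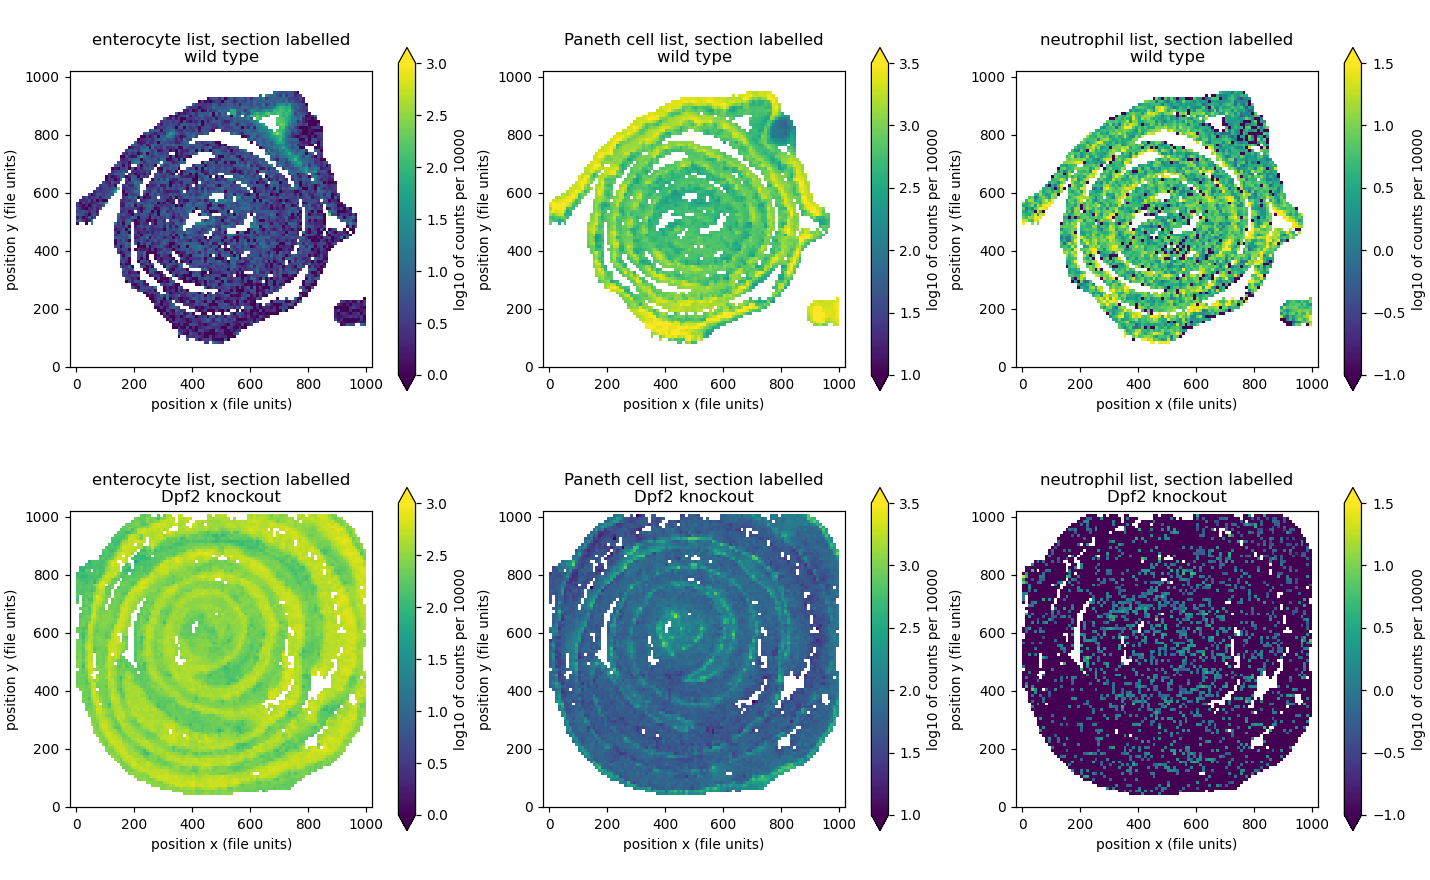
Maps of both sections in squares with a side of 10 position units and at least 1000 counts, coloured by the log10 of the counts of the enterocyte, Paneth cell and neutrophil lists per 10000 counts, with 1 colour scale per list for both sections. Tiles of the section labelled knockout hold 13588 to 53957 CPM of enterocyte genes, against 156 to 4428 CPM in tiles of the section labelled wild type.

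Genes of cell division were lower in the section labelled knockout. All 30 proliferation genes had ratios below 0, with a median of −0.80 (−1.09 to −0.71), and 11 were at least 2-fold lower. The ribonucleotide reductase subunit Rrm2 stood at −1.93, the kinase Cdk1 at −1.89, Tubb5 at −1.89 and the replication helicase subunit Mcm3 at −1.73. Within shared region 2, one of the regions found in both sections, the median was −0.03. Of the 30 genes, 19 lay less than 2-fold apart over all spots and could help to form this region. Its median is therefore no separate test of the direction. Genes of DNA damage response and repair had a median of −0.63 (−0.74 to −0.39), with 26 of 30 lower. Brca1 stood at −1.33 and Fancd2 at −1.43, while Lig4 at 1.77 was higher. Their median was −0.79 in shared region 1, with 26 of 30 lower, and −1.02 in spots with a pan-epithelial share of 1.27% or more. Within shared region 2, 15 of these 30 genes were higher and 15 lower, and the median was −0.13 in shared region 3 and 0.03 in shared region 4. Of the 30, 22 lay less than 2-fold apart over all spots and could help to form the regions, so the medians within regions are no separate test here either. The p53 targets had a median of −0.50 (−0.94 to 0.04), with 19 of 29 lower. Plk2 stood at −3.32, Gdf15 at −3.08 and Bax at −1.48, the cell cycle inhibitor Cdkn1a at −0.51, and the BH3-only gene Pmaip1 at 1.53 and Sesn1 at 1.49. Genes of apoptosis had a median of 0.27 (−0.32 to 1.28), with Casp6 at 3.09 and Cycs, which encodes cytochrome c, at 1.69. Genes of the Wnt pathway had a median of −0.10 (−1.02 to 0.83), which turned to 0.08 with scaling by the median of ratios. Myc stood at −2.07 and Ccnd1 at −1.25, and Tcf7l2 at 1.18. Genes of the Notch pathway had a median of −0.21 (−1.21 to 0.98), with Notch2 at −1.94 and Dll4 at 1.06.

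Genes listed for the regenerating state that epithelium enters after injury, associated with YAP, were lower in the section labelled knockout in 23 of 25 cases. Their median was −2.56 (−3.34 to −2.10), below every matched random list, and their sum was 0.525% of counts (0.523 to 0.527) in the section labelled wild type and 0.151% (0.151 to 0.152) in the section labelled knockout. The growth factor Ereg had 884 and 12.1 CPM, a ratio of −6.20. Spp1 stood at −5.13, Sprr1a at −4.27 and Ly6a, which encodes the surface protein SCA-1, at −4.26. Each of the 65 tiles of the section labelled wild type held more of this list, 3245 to 6922 CPM, than any of the 92 tiles of the section labelled knockout, 859 to 2338 CPM.

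Inflammatory genes were also lower in the section labelled knockout. NF-kB and inflammatory mediators had a median of −2.70 (−5.42 to −1.08), with 23 of 26 lower. The cytokine genes Il1b at −7.43 and Il6 at −7.32 and the prostaglandin synthase Ptgs2 at −6.64 stood beside the chemokines Cxcl1 and Cxcl2, and the inhibitor Nfkbia stood at −1.32. Neutrophil genes had a median of −6.08 (−8.12 to −1.95), with 11 of 12 at least 2-fold lower, including S100a9 and Retnlg at −6.79. Their sum ranged from 242 to 1500 CPM over the tiles of the section labelled wild type and from 7.69 to 71.4 CPM over those of the section labelled knockout. Genes of macrophages and dendritic cells had a median of −1.42 (−2.40 to −0.97), with 16 of 17 lower, among them Cd14 at −4.40, Tyrobp at −3.17, the complement gene C1qb at −2.42 and Apoe at −1.42. Mast cell genes had a median of −1.54 (−3.73 to 1.83), with the protease Mcpt2 at −3.73. B cell genes had a median of −3.96 (−6.42 to −2.95), with Ighd at −6.42, Ighm at −3.75 and Cd79a at −4.16. The sum of B cell genes differed between parts of the section labelled wild type, from 34.3 to 344 CPM. Plasma cell genes had a median of −0.92 (−1.34 to 0.04), with Igha at −1.19 and Igkc at −1.30. Genes of T and NK cells had a median of 1.10 (−0.35 to 2.33), with the granzymes Gzma at 3.02 and Gzmb at 3.04 and Cd3g at 2.92, and with Il7r at −2.80 and Cd2 at −2.87.

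Immune response genes beyond these lists went both ways. Interferon response genes had a median of −0.26 (−0.82 to 0.34), with Ifitm3 at −3.34, Cxcl10 at −2.77 and Bst2 at −2.57, and with the transcription factor Irf1 at 2.12 and Ifi27l2b at 1.97, while their summed level stood at 0.03. Genes of MHC class I presentation had a median of 1.23 (−0.11 to 6.62), with H2-K1 at 1.14 and B2m at 1.10. The nonclassical genes H2-T3 and H2-Q1 stood at 7.11 and 6.62, and the activator Nlrc5 at −1.81. Genes of MHC class II presentation had a median of −0.31 (−2.53 to 0.63), with H2-Aa at −0.66 and H2-Ab1 at 0.63. Genes of pyroptosis and the inflammasome had a median of 0.23 (−1.37 to 2.35). Il18 at 4.15, Nlrp6 at 3.34 and Gsdmd at 2.35 were higher, and Il1b and Nlrp3 at −3.44 were lower. Immediate early and heat shock genes had a median of −0.89 (−1.45 to −0.31), with the phosphatase Dusp1 at −4.86, Ier3 at −4.38 and Egr1 at −3.28.

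Genes of tissue other than epithelium and immune cells differed by cell type. Smooth muscle genes were higher in the section labelled knockout in all 14 cases, with a median of 1.18 (0.81 to 1.83), including Acta2 at 1.46 and Tagln at 1.83. Within shared region 3, 7 of them were higher and 7 lower, with a median of 0.04. Adipocyte genes had a median of 6.11 (1.42 to 12.07), with Retn at 7.64 and Plin1 at 6.11. Their sum ranged from 187 to 11394 CPM over the tiles of the section labelled knockout and did not exceed 30.7 CPM in a tile of the other. Whether this fat belongs to the gut wall or to mesentery caught with 1 section was not tested. Erythrocyte genes had a median of 2.16 (range 1.33 to 2.21). Genes of extracellular matrix and fibrosis were lower in all 22 cases, with a median of −1.78 (−3.31 to −0.83). The matrix metalloproteinases Mmp3 at −6.56 and Mmp10 at −5.50 led them, and Col1a1 stood at −0.60. Fibroblast genes had a median of −0.76 (−1.38 to −0.08), with Sparc at −1.71 and the BMP antagonist Grem1 at −1.61. Endothelial genes were lower in all 12 cases, with a median of −1.17 (−1.60 to −0.60), such as the VEGF receptor Flt1 at −2.07, with 8 of 12 lower and a median of −0.12 in shared region 4. Lymphatic endothelial genes had a median of −1.75 (−3.15 to −0.87), with Pdpn at −3.15 and Lyve1 at −2.58. Enteric neuron genes had a median of −0.76 (−1.32 to −0.59), with the neuropeptides Vip at −2.47 and Gal at −2.28. Enteric glia genes had a median of 1.28 (−2.26 to 5.56), with Entpd2 at 2.11 and Gfap at −2.26. Their sum in the section labelled knockout is mostly that of Erbb3, which had a tile median of 199 CPM beside 238 CPM for the list, and its cell source was not tested. Genes of interstitial cells of Cajal had a median of −0.04 (range −1.48 to 0.56), positive with scaling by the median of ratios, with Kit at −0.42 and Ano1 at −1.48. Mesothelial genes had a median of 0.18 (−3.79 to 1.45), with Msln at −3.79 and Upk3b at 1.45, while their summed level stood at −2.29. Markers of neighbouring organs had few measured members. Those of pancreatic acinar cells had a median of −0.43 (range −2.68 to 4.21), with Clps at −1.93. Their summed level of 3.42 is mostly that of Zg16, named above among goblet cell genes, which gave 293045 of the 296627 counts in the section labelled knockout. Genes of gastric and Brunner gland cells had a median of −3.16 (range −5.29 to −0.59), with Gkn1 at −4.43.

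Genes of fatty acid oxidation and of oxidative phosphorylation were mostly higher in the section labelled knockout. Fatty acid oxidation and PPARA targets had a median of 1.55 (0.16 to 2.56), with 15 of 19 higher, Vnn1 at 5.47 and Ppara at 2.97. Nuclear genes of oxidative phosphorylation had a median of 0.82 (0.42 to 0.97), with 18 of 19 higher and Cox4i1 at 0.82. NRF2 and antioxidant genes had a median of 0.77 (−0.21 to 1.55), with Gstm3 at 6.31 and the catalase Cat at 2.87, and with Hmox1 at −2.79, while their summed level stood at −0.03. Genes of ferroptosis and iron had a median of 0.47 (−0.37 to 0.90), with the lipid peroxide reductase Gpx4 at 1.63 and the cystine transporter Slc7a11 at −2.54, while their summed level stood at −0.31. Genes of the unfolded protein response had a median of 0.43 (−0.15 to 0.87), with Ddit3 at 1.39 and Asns at −1.94. Hypoxia genes had a median of 0.41 (−2.82 to 1.25), with Ldha at 1.25, and with Hilpda at −3.51 and Adm at −3.23. Cholesterol synthesis genes had a median of −0.38 (−0.93 to −0.16), with 15 of 18 lower and Lss at −1.86. In shared region 3, 9 of them were higher and 9 lower, with a median of −0.14 (−0.69 to 0.22), and the median was −0.17 (−0.55 to 0.15) in shared region 2.

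Clustering of 131989 spots from both sections gave 8 regions. None held 100 or more spots of each section, and each took more than 90% of its spots from 1 section. The section labelled wild type held a region led by the defensins Defa2 and Defa21, with 49.4% of its spots, and a region led by Tff1 and Mucl3, with 48.0%. Regions led by Ighd and Fcmr and by Slfn4 and Bmp2 held 1.37% and 1.18% of its spots. The section labelled knockout held regions led by Slc28a2 and Tmprss15 (40.8%), by Camk1d and CT010467.1 (34.8%), by Optc and Galr2 (18.4%) and by Cyp2e1 and Adipoq (5.99%). Median counts per spot were 1129, 626, 1168 and 1259 in these regions, in this order. They were 884, 639, 741 and 971.5 in the regions of the section labelled wild type, in the order named. Whether depth helped to form the regions was not tested. Genes of the epithelium were also counted in regions led by genes of other tissue. In the section labelled knockout, the regions led by Optc and by Cyp2e1 held 221 and 243 enterocyte counts per 10000, beside 489 in the region led by Slc28a2. In the section labelled wild type, the region led by Ighd held 122 Paneth counts per 10000, beside 1812 in the region led by Defa2.

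When the clustering left out genes 2-fold or more apart between the sections, 4 of 5 regions had at least 100 spots of each section and are called shared here. Shared regions 1 and 4 still took 96.9% and 93.2% of their spots from the section labelled knockout. Enterocyte, Paneth cell, regenerative and neutrophil medians kept their direction within each of the 4. All 23 enterocyte genes and all but 1 of 20 Paneth cell, 5 of 25 regenerative and 1 of 12 neutrophil genes were 2-fold or more apart and so could not shape these regions. Spots were thus not grouped by them, and their ratios within regions are no separate test of the differences. Shared region 1, led in both sections by Slc28a2 and Apoa4, held 2.89% of spots in the section labelled wild type and 50.4% in the section labelled knockout. Shared region 2, led by Dmbt1, Spag5 and the centriole kinase Plk4, held 66.5% and 11.8%. Shared region 3, led by Defa21, Defa32 and Camk1d, held 27.5% and 20.5%, and shared region 4, led by Gal, Tpm2 and Des, held 2.26% and 17.3%. These shares describe 1 section each, and no claim of a difference between genotypes rests on them. Median counts per spot were 1068, 813, 526 and 1344 in shared regions 1 to 4, so region 3 holds the spots of least depth among them. Enterocyte genes had medians of 4.66, 5.51, 6.80 and 5.54 in shared regions 1 to 4, and Paneth cell genes −4.39, −3.55, −4.17 and −3.26. Regenerative genes had medians of −3.56, −2.63, −2.48 and −1.98, NF-kB and inflammatory mediators −3.03, −2.04, −3.17 and −2.07, and neutrophil genes −7.27, −5.52, −6.23 and −5.63. Proliferation genes had medians of −1.13, −0.03, −0.28 and −0.33, and stem cell genes −0.71, 0.11, −0.01 and 0.25. Most proliferation genes lie less than 2-fold apart and could shape these regions, and whether that brought their medians in regions 2 to 4 closer to 0 was not tested.

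**Figure D3:**
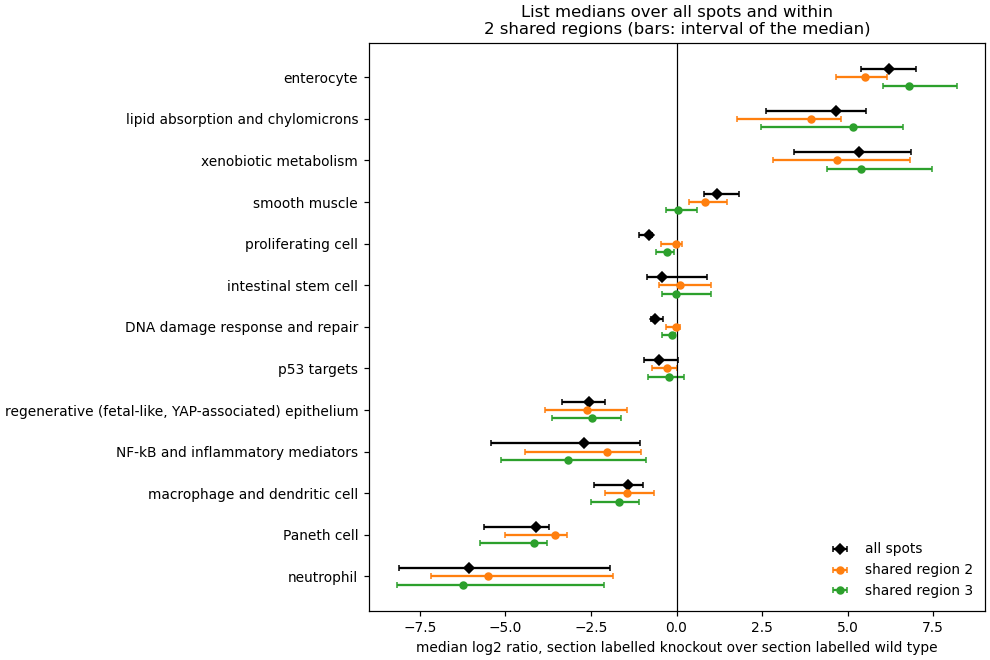
Median log2 ratios of 13 lists over all spots and within shared regions 2 and 3, section labelled knockout over section labelled wild type, with the interval of each median as bars. Enterocyte, Paneth cell, regenerative and neutrophil medians keep their side of 0, while the proliferation median moves from −0.80 over all spots to −0.03 in shared region 2.

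The lowest and highest ratios of single genes within the shared regions are given here, and since they were picked as extremes they test nothing. In shared region 1, Cxcl2, S100a9 and S100a8 had the lowest ratios at −9.14, −9.12 and −8.91, and Leap2, Lct and Treh the highest at 8.89 (6.42 to 14.20), 8.61 and 8.19 (6.34 to 11.24). In shared region 2, Ly6g stood at −9.25 (−14.56 to −6.77) on 1 count in the section labelled knockout, Cxcl2 at −8.97 (−11.25 to −7.42) and Cxcl1 at −8.45 (−11.50 to −6.60). Cfd at 10.21, Cyp1a1 at 9.25 (7.38 to 12.30) and Mbl2 at 8.89 were the highest there. In shared region 3, Cxcl2 stood at −9.41, Retnlg at −8.68 (−13.99 to −6.19) and Cxcl1 at −8.39, and Cfd at 12.35 (9.88 to 17.66), Cyp2d26 at 11.13 (8.65 to 16.43) and Lct at 11.11. In shared region 4, Cxcl2 at −11.01 (−14.07 to −9.14), S100a8 at −7.67 and Il1b at −7.62 were the lowest, and Leap2 stood at 8.19 (5.71 to 13.50). Cfd and Lct had 0 counts there in the section labelled wild type and 52481 and 13326 counts in the section labelled knockout.

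Restricting both sections to spots with a higher share of pan-epithelial counts left 53 of 57 lists on the same side of 0 as over all spots. The others were BAF complex subunits at −0.11, MHC class II presentation at 0.15, mesothelial genes at −0.41 and genes of interstitial cells of Cajal at 0.06. Spots at or above the median share of pan-epithelial counts, 0.944%, numbered 14964 (29.4%) in the section labelled wild type and 54549 (61.9%) in the section labelled knockout. Over these spots, enterocyte genes had a median of 5.78 (4.93 to 6.42), Paneth cell genes −3.80 (−5.29 to −3.43), and regenerative genes −3.04 (−3.77 to −2.45). NF-kB and inflammatory mediators had −2.71 (−5.34 to −0.99) and neutrophil genes −6.07 (−8.17 to −1.97). Proliferation genes had a median of −1.23 (−1.50 to −1.10), p53 targets −0.60 (−1.13 to −0.20), stem cell genes −0.76 (−1.07 to 0.36) and goblet cell genes −0.27 (−1.13 to 2.09). At medians of 721 and 932 counts per barcode, a share of 0.944% rests on few counts, so the split is coarse. The pan-epithelial genes also differed between the sections. The restriction therefore does not match the sections for epithelium and is no separate test of the lists.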

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

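The alternatives restricted to region 2 or 3 of the clustering without genes 2-fold apart, and the division by the proliferation list sum, were chosen only after the results were seen. Dpf2 stood at 0.32 with scaling by the median of ratios, 0.021 in spots with a pan-epithelial share at or above the median and 0.36 in region 2; the cause was not tested. Genes at least 2-fold lower numbered 1651 with a minimum of 1000 counts, which leaves 10320 genes to count. The proliferation median was −0.62 with scaling by the median of ratios, which adds 1 factor to all genes. It was −1.23 in spots with a pan-epithelial share at or above the median, −1.54 as a list sum over the pan-epithelial sum, −0.025 in region 2 and −0.28 in region 3; the cause was not tested. Regenerative genes stood at −1.79 as summed CPM. Over the proliferation sum, which is itself lower in the section labelled knockout, they stood at −0.81, p53 targets at 0.66, Paneth cell genes at −2.87 and endothelial genes at 0.32, the last reversed. Enterocyte genes stood at 5.25 over the pan-epithelial sum and Paneth cell genes at −3.55 in region 2; the cause was not tested. Clustering gave 3 regions at resolution 0.3 and 5 without genes 2-fold apart. Values at least 2-fold apart are called reversed where they change sign. Of the other 360 named genes, 278 were that far apart, and 0 of their 1945 comparisons reversed. Of the 82 genes less than 2-fold apart, 15 changed sign, in 25 of 574 comparisons. Of the other 50 lists, 23 were at least 2-fold apart, and 1 of their 295 comparisons reversed, that of endothelial genes. Of the 27 lists less than 2-fold apart, 18 changed sign, in 43 of 350 comparisons, so their directions depend on the processing. Beyond sign, 895 of 2519 comparisons of genes moved past the counting interval and 55 of 645 comparisons of lists past the interval of the median. Leaving out mitochondrially encoded genes moved nothing, since they hold 0 counts, so this alternative checks nothing. Mitochondrial RNA counted under other genes, if there is any, would stay in the main totals. Whether the predicted genes among the most abundant hold such RNA was not tested. The total without the 50 most abundant genes of each section leaves these out, and the enterocyte median was 6.10 with it. No paired analysis was possible because each group has 1 section, and the numbering of the samples pairs nothing. Depth limits genes near the floors of 0.0753 and 0.0334 CPM.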

Other observations

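Of the tests in this part, that of a deletion in the epithelium was set before its result was seen, and the other 7 were chosen only after.

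Of the 10 most abundant genes of each section, 5 were shared. The predicted gene Gm28437 had 13827 CPM in the section labelled wild type and 31018 CPM in the section labelled knockout, a log2 ratio of 1.17. The predicted genes Gm10925 and Gm29216 stood at 0.50 and 0.49, Myo3a, which encodes a myosin, at 1.02, and Nkain2 at 0.15. Abundant only in the section labelled knockout by this rule were Gm28661 at 0.74, Sprr2a2, a small proline-rich protein of epithelium, at 1.03, Tlk1 at 0.06, Reg3b at 4.04 and Trim30a.

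Enterocyte genes were lower in the section labelled wild type. A difference in depth or a few dominant genes is argued against as the whole cause, since the enterocyte median stayed between 6.07 and 6.38 over 5 alternatives on scaling, dominant genes and spot depth. The rescalings among these shift all genes by 1 factor, so they could not have removed a difference confined to some genes. A loss of enterocytes with all other tissue unchanged would move other cell types together, but the smooth muscle median lay 5.27 above the Paneth cell median (4.55 to 7.45), so it cannot be the whole cause. A stretch of colon in the section labelled wild type would lower Paneth cell genes there, but these had a median of −4.09, meaning higher there, with the colon median at 0.99. Open are an effect of the Dpf2 genotype, an unequal time or severity of injury and another stretch of small intestine, any of which may give this pattern and none of which the design of 1 section per genotype can separate.

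Dpf2 was not lower in the section labelled knockout, at 0.14 on the log2 scale. A deletion limited to the epithelium and diluted by other tissue could lower Dpf2 in spots rich in epithelial RNA. In the section labelled wild type, Dpf2 had 25.9 CPM in spots with a pan-epithelial share of 1.27% or more and 23.2 CPM in spots at 0.641% or less, against 24.7 and 29.1 CPM in the section labelled knockout. The difference in log2 was −0.39 (−0.73 to −0.02), short of the limit of −0.5 set beforehand, so it decides nothing. In the spots rich in epithelial RNA, the counting intervals overlapped, at 21.5 to 31.0 CPM in the section labelled wild type and 22.9 to 26.7 CPM in the section labelled knockout. Most of the difference lay in the spots at 0.641% or less, where Dpf2 was higher in the section labelled knockout. Exchanged labels cannot be told apart from reads that fall outside the deleted part, since a ratio of 0.14 is far from 1 in either direction.

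Paneth cell genes differed by unequal amounts. Reads shared among near-identical defensin genes cannot be the whole cause, since 5 genes outside that family were up to 3.06 apart. These ran from Mmp7 at −5.61 over Lyz1, Itln1 and Habp2 to Ang4 at −2.55, and were named after their values were seen. They were taken because they were at least 2-fold lower in the section labelled knockout. They say nothing about the unequal ratios among the defensins themselves. Fewer Paneth cells by 1 common factor would keep the ratios between Paneth cell genes, if only Paneth cells express them. For 9 of 19 genes, the ratio to Defa24 had tile ranges that did not overlap between the sections, which argues against such a factor as the whole cause. Named after their values were seen, these were Defa20, Defa21, Defa22, Defa29, Defa3, Defa5, Gm14851, Mmp7 and Guca2b. Of them, only Mmp7 and Guca2b were counted outside the defensin family. Guca2b was higher in the section labelled knockout, against the direction of the list, and whether only Paneth cells express it was not tested. Without Guca2b, Mmp7 is the only gene outside that family that argues against 1 common factor. A difference in position along the gut may give unequal ratios and stays open: the ratio of Defa20 to Defa24 was at least 0.103 in every tile of the section labelled wild type and at most 0.0625 in every tile of the section labelled knockout, and the sections may come from different stretches. The genotype, and a strain difference in the defensin genes, were not tested and stay open too.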
